A study of Homo sapiens with 4 samples.

How the data were processed

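The series holds 4 Illumina bead arrays of biotin-labelled RNA from L591 cells, 2 transfected with an empty expression plasmid (mock) and 2 with PDLIM2 transcript variant 2, each together with a GFP plasmid and sorted for GFP. The groups and the array numbers were taken from the sample titles. The labels give the extracted molecule as polyadenylated RNA. The authors deposited 1 log2 value per probe and array, and scanner software, background correction and normalization are not given in the sources used here. The deposited log2 values share nearly the same quartiles on all 4 arrays (75th percentile 7.553 on each), so they were used as deposited under the rule set for values whose quartiles agree within 0.05 log2 units. Signal over background and detection p-values were not used here, so how far a dim probe lies above background is unknown.

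The table held 47231 probes. A probe with an empty cell in the mock array 2 was left out, which left 47230 complete probes. In GEO's platform annotation 30113 probes had 1 gene symbol, 8 had several and were left unnamed, and 17110 were not listed. Symbols were updated through RefSeq (GRCh38.p14), which also gave the kind of gene and was used for nothing else. Among the genes of the lists, 2 older symbols were updated this way.

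Probes whose mean log2 value over the 4 arrays was above the median of all probes (5.99) were tested, 23615 in number, of which 16913 had a symbol, for 12417 genes. PDLIM2 lay under this filter, and its values come from the same fit on all 47230 probes. Differences are PDLIM2 minus mock, fitted with lmFit and eBayes of limma 3.58.1 in R 4.3.3 without trend, robust prior or replicate number, and p-values are two-sided with Benjamini-Hochberg adjustment at 0.05. The fit had 2 residual degrees of freedom and a prior worth 5.10 more. Counts of probes past 1.5-fold at an unadjusted p under 0.05 are descriptions, set beside the other 2 splits of the arrays.

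The 17 gene lists, the filter, the tests and the rule for named genes were fixed before the data were examined. The lists were tested with camera of limma at an inter-gene correlation of 0.01, using for each gene its brightest tested probe, with adjustment over the 17 lists. The named genes are PDLIM2, the 10 genes per direction that pass the adjusted threshold with the largest difference, with places left open filled by the smallest unadjusted p among genes of at least 1.5-fold difference whose groups do not overlap, and up to 4 members of each list, or the 2 with the smallest p where none passed. Genes with placeholder symbols were skipped. No gene passed, so all named genes are given as values. BCL6, TNF, HSPA1A, HSPA1B and the further genes of the additional observations were named after their values were seen. For SOCS3 and HBP1 both tested probes had the same sign.

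The scripts were tested on simulated arrays with the means of the 23615 tested probes, in which 100 probes were changed 2-fold and 100 4-fold. With independent arrays and each probe's own moderated variance, the fit recovered 81 of the 2-fold and 100 of the 4-fold changes with 27 false calls, which was 13.0% of its calls and above the nominal 5%. Because of that, variances were drawn from the fitted prior in a second simulation, and the fit then recovered 9 of the 2-fold and 96 of the 4-fold changes with 4 false calls (3.67%). Both versions are kept, since the second was added after the first was seen. A shift shared by arrays of the same number was also simulated, set to each probe's estimated difference between the numbers. The fit without the number then recovered 4 (own variance) and 0 (prior variance) of the 2-fold changes. It recovered 91 and 82 of the 4-fold changes, with 0 false calls in both. The estimated difference includes noise, so the simulated shift may be larger than the real one and the recovery understated.

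The alternatives tried were no filter, a filter at the 75th percentile, quantile normalization, median centring, an offset of 50 added to the intensity, limma-trend, a robust prior, the replicate number as a block, each array left out in turn, an estimated correlation in camera, fry, and the mean over all probes of a gene. After the data were seen, the AP-1 list without FOSB and the heat shock list without BAG3 were added.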

Results

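L591 cells, a line derived from Hodgkin lymphoma, received either an empty expression plasmid (mock, pcDNA3) or the same plasmid carrying transcript variant 2 of PDLIM2, a protein with a PDZ and a LIM domain that is a putative ubiquitin ligase. The amount was 40 µg of the expression plasmid with 10 µg of a GFP plasmid, and GFP-positive cells were sorted before RNA was taken. Each group had 2 Illumina bead arrays, numbered 1 and 2 in the labels, which makes 4 arrays in all. Each array had a log2 value for 47230 or 47231 probes, and the median value lay between 6.006 and 6.007 on all of them. The number of arrays limits the precision of every difference given here. The labels do not say that the 2 arrays of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

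The comparison asks which transcripts differ in L591 cells that were given PDLIM2. PDLIM2 itself had 2 probes, both dim, and they differed in opposite directions. The brighter probe (ILMN_1669667) read 5.33 ± 0.24 log2 units in the mock arrays and 5.64 ± 0.17 in the PDLIM2 arrays (mean ± SD, n = 2 each), a difference of 0.31 (SE 0.18). The other probe (ILMN_1770248) read 5.55 ± 0.10 in the mock arrays and 5.25 ± 0.02 in the PDLIM2 arrays, a difference of -0.29 (SE 0.15). Both lay under the brightness filter, at percentiles 6.14 and 2.99 of all probes, and in a limma fit on all probes the adjusted p of each was 0.9998. The probes are annotated to different PDLIM2 transcripts, and whether either lies within the transfected cDNA was not determined here, so neither checks the labels.

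The genes with the clearest higher values in the PDLIM2 arrays were mostly small noncoding RNAs. The labels give the extracted molecule as polyadenylated RNA, so whether small RNA values follow the levels in the cells is not known. RNA5S9, a 5S ribosomal RNA gene, was 3.72-fold higher (log2 difference 1.90, SE 0.29), and RNU6ATAC, a small nuclear RNA of the minor spliceosome, was 3.18-fold higher (1.67, SE 0.28). SCARNA23, which belongs to the small RNAs of Cajal bodies, had a log2 difference of 1.34 (SE 0.29). SOCS3, a feedback inhibitor of JAK-STAT signalling, was 2.07-fold higher, at 8.91 ± 0.10 in the mock arrays and 9.96 ± 0.02 in the PDLIM2 arrays (log2 units, mean ± SD, n = 2 each), while its dimmer probe differed by 0.45 (SE 0.24), or 0.12 without the PDLIM2 array 2. The vault RNA VTRNA2-1 differed by 1.00, the Y RNA RNY4 by 0.93, the nucleolar RNAs SNORA11B, SNORD83B and SNORA75 by 1.03, 0.93 and 0.86, and NRROS, a regulator of reactive oxygen species, by 0.86 log2 units. None of these 10 genes passed the adjusted threshold (limma, adjusted p = 0.9998 for each). They were picked among genes whose groups do not overlap, so that separation is no further evidence.

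The genes with the clearest lower values in the PDLIM2 arrays were protein-coding. TSC22D3, a leucine zipper protein induced by glucocorticoids, read 11.81 ± 0.61 log2 units in the mock arrays and 10.05 ± 0.31 in the PDLIM2 arrays (mean ± SD, n = 2 each), a difference of -1.76 (SE 0.31), and all 3 of its tested probes were lower. HBP1, a transcriptional repressor, differed by -1.27 (SE 0.22) and FBXO32, a substrate-binding subunit of a ubiquitin ligase, by -1.26 (SE 0.18), which put them at 0.415 and 0.417 times their mock level. The dimmer probes differed by -1.23 (HBP1) and -0.78 (FBXO32). RPS6KA5, a kinase activated by stress and mitogen signals, differed by -1.17 (SE 0.19), and IL10RA, the ligand-binding chain of the interleukin-10 receptor, by -1.11 (SE 0.18). The kinase gene MAK differed by -1.14, HYCC2 by -1.10, ZNFX1 by -0.98, the ubiquitin ligase gene PELI1 by -0.92 and the zinc finger gene ZFX by -0.87. None of these 10 genes passed either (limma, adjusted p = 0.9998 for each), and they were picked by the same rule.

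**Figure D1:**
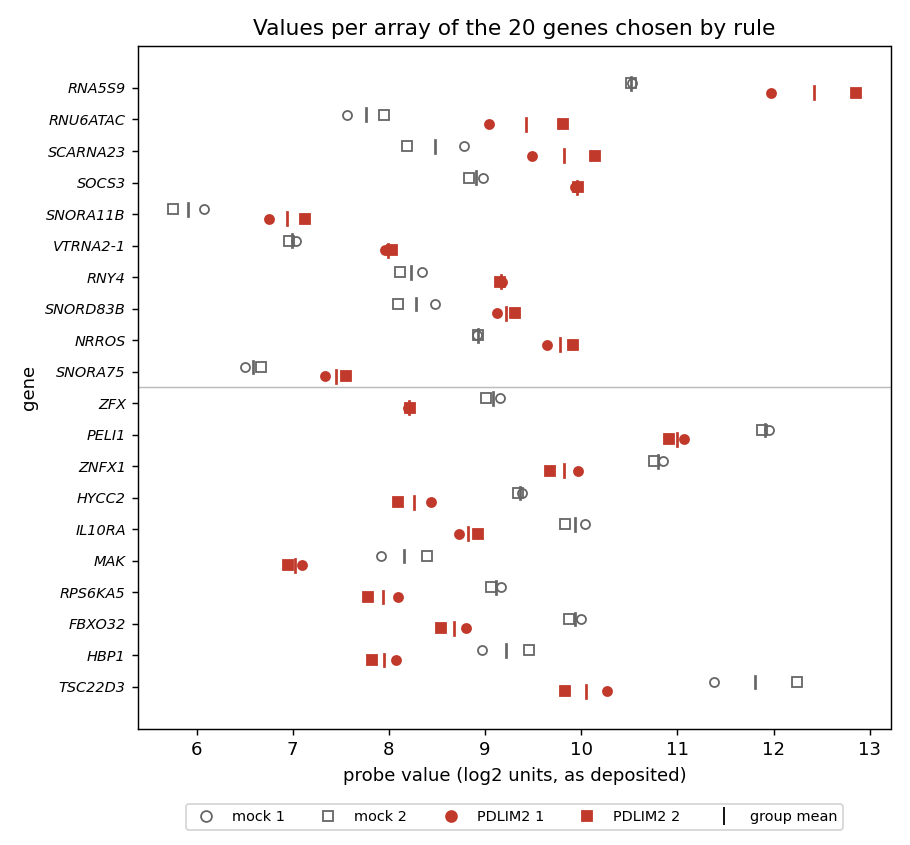
Deposited log2 value (horizontal axis) of the 20 genes chosen by rule, 10 with higher and 10 with lower values in the PDLIM2 arrays, ordered by the difference. Open grey symbols are mock arrays, filled red symbols PDLIM2 arrays, circles number 1 and squares number 2, and vertical ticks the group means. RNA5S9 shows a mean of 10.52 in the mock and 12.42 in the PDLIM2 arrays, and TSC22D3 a mean of 11.81 and 10.05.

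Over 23615 tested probes (12417 named genes), limma called 0 probes higher and 0 lower with PDLIM2 at an adjusted p under 0.05, and 665 probes (2.82%) had an unadjusted p under 0.05, where 1181 would be expected by chance. No probe was called with the trended or the robust variance prior. Among the 665 were 254 probes with higher values, RNA5S9 and SOCS3 among them, and 411 with lower values, FBXO32 and TSC22D3 among them. At a difference of at least 1.5-fold as well, there were 84 probes with higher and 229 with lower values, or 46 and 152 with an offset of 50 added to the intensity. The other 2 ways of splitting the 4 arrays into pairs gave 619 and 479 such probes between the arrays numbered 2 and those numbered 1, and 13 and 17 in the remaining split. Between the numbers, 3918 probes (16.6%) had an unadjusted p under 0.05, and limma called 4 higher and 3 lower in number 2. This difference between numbers adds to the residual spread of the PDLIM2 fit. Arrays were simulated with such a shift, set to its estimate with noise included and so perhaps too large. On these, that fit recovered 4 (own variance) and 0 (prior variance) of 100 2-fold changes. Hence 0 calls do not exclude changes of that size. The 2 PDLIM2 values lay above both mock values for 3723 probes and below them for 3033, together 28.6% of the tested probes, and chance gives 33.3%. A fit with an array left out has 1 array alone in its group and cannot measure that group's spread. It also unbalances the array numbers. The counts of such fits moved with the array left out, and no conclusion is drawn from them.

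Target genes of NF-kB, the transcription factor family that drives survival and cytokine genes in Hodgkin cells, were not called as a list. Of the 32 measured members, 16 had higher and 16 had lower values, with a mean log2 difference of -0.029 (SD over members 0.27; camera in limma, adjusted p = 0.770). No member passed the test over all probes and 0 passed adjusted over the list alone. IRF1, an interferon regulatory factor, differed by -0.84 (SE 0.19) and CD83, a marker of activated B cells and dendritic cells, by -0.65 (SE 0.19). The cytokine gene TNF, which the rule for named genes did not select, had a value of 0.49 (SE 0.17) in the other direction. The list mean changed sign with the array left out: it was -0.168 without the mock array 2, 0.109 without the mock array 1 and 0.023 without the PDLIM2 array 2.

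JAK-STAT target genes moved in both directions. The mean log2 difference of the 18 measured members was -0.040 (SD 0.44; camera, adjusted p = 0.770), with 7 higher and 11 lower values. Adjusted over the list alone, 3 members passed in limma, and 0 passed over all probes. SOCS3 was the member with a higher value (log2 difference 1.05, list-adjusted p = 0.00738 in limma). The lower ones were PIM1, a survival kinase (-0.85, list-adjusted p = 0.0146 in limma), and BCL6, a germinal centre repressor (-0.62, list-adjusted p = 0.0488 in limma). The mixed test of fry in limma, which asks whether members differ in either direction, gave an adjusted p of 0.0277 for this list, and its one-directional test gave 0.996. The list mean was 0.041 without the mock array 1.

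Heat shock genes and the AP-1 family with its targets were lower as lists in the PDLIM2 arrays. The 16 measured heat shock genes had a mean log2 difference of -0.30 (median -0.13, SD over members 0.48; camera, adjusted p = 0.0266), with 11 lower and 5 higher values. This call was lost with an estimated correlation between genes (camera, adjusted p = 0.902). The co-chaperone genes BAG3 (-1.42, SE 0.29) and DNAJB4 (-0.88, SE 0.19) both passed adjusted over the list alone (limma, list-adjusted p = 0.0157 each), and 0 passed over all probes. The 20 measured AP-1 genes had a mean of -0.23 (median -0.10, SD 0.53; camera, adjusted p = 0.0435), with 13 lower and 7 higher values and 0 members past the test over all probes or adjusted over the list alone. This call too was lost with an estimated correlation (camera, adjusted p = 0.902). The estimate for the AP-1 list was -0.047, below the fixed 0.01, so its loss is no sign of correlation between its genes. For the heat shock list the estimate was 0.56, above the fixed 0.01, so its call may treat its genes as too independent. The unadjusted p with the estimated correlation was 0.384 for the heat shock list and 0.0926 for the AP-1 list (camera). Under that setting camera gave every list an adjusted p between 0.902 and 0.979. FOSB, an immediate early transcription factor, had the value -2.10 (SE 0.83), with 9.56 and 11.91 log2 units in the mock arrays 1 and 2 and 7.64 and 9.63 in the PDLIM2 arrays 1 and 2, so the groups overlapped. FOSB was higher in array 2 in both groups. PDLIM2 minus mock was -1.93 between the arrays numbered 1 and -2.28 between those numbered 2. Leaving an array out unbalances the numbers. The difference was then -0.93 without the mock array 2 and -1.11 without the PDLIM2 array 1, and -3.27 and -3.10 without the mock array 1 and the PDLIM2 array 2. The fit with the replicate number as a block called FOSB lower, and over 5% of that fit's calls were false on simulated arrays. ATF3, a stress-induced transcription factor, had the value -0.81 (SE 0.32), which was -1.31 without the PDLIM2 array 1 and -0.31 without the PDLIM2 array 2. The AP-1 list was not called without FOSB (mean -0.13, adjusted p = 0.128) nor the heat shock list without BAG3 (mean -0.22, adjusted p = 0.128), both in camera and chosen after seeing the data. The heat shock mean was -0.063 without the mock array 1 (camera, adjusted p = 0.536) and -0.053 without the PDLIM2 array 2 (adjusted p = 0.503), and -0.54 and -0.53 without the PDLIM2 array 1 and the mock array 2. Within the groups the heat shock mean differed from array 1 to array 2 by -0.46 (mock) and -0.49 (PDLIM2), more than between the groups. Both moves went the same way, so the mean with an array left out shifts with that array's number. PDLIM2 minus mock was -0.29 between the arrays numbered 1 and -0.31 between those numbered 2. The AP-1 mean was -0.14 without the mock array 2 (adjusted p = 0.0902) and -0.19 without the PDLIM2 array 1 (adjusted p = 0.0719). HSPA1A and HSPA1B are near-identical genes, so the values of their probes are uncertain.

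**Figure D2:**
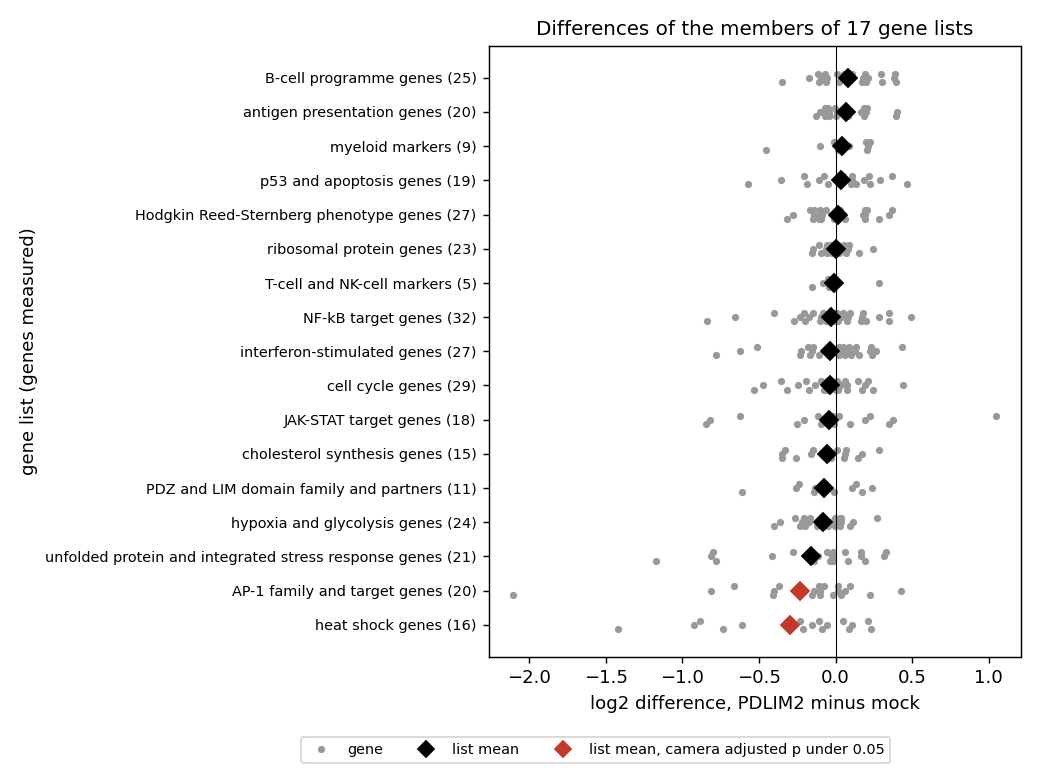
Log2 difference, PDLIM2 minus mock, of the measured members (grey points) and mean (diamonds) of the 17 gene lists, with the number of genes measured in brackets. The red diamonds are the 2 lists with a camera adjusted p under 0.05, heat shock genes at -0.30 and AP-1 genes at -0.23, and the point at -2.10 is FOSB.

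Camera called none of the other 13 gene lists, with adjusted p between 0.128 and 0.952. Genes of the unfolded protein and integrated stress responses had a mean log2 difference of -0.16 over 21 measured genes (adjusted p = 0.244). PPP1R15A, a phosphatase subunit of that response, had the value -1.17 (SE 0.34), which was -0.62 without the PDLIM2 array 2. That list's mean was -0.34 without the PDLIM2 array 1, -0.21 without the mock array 2 and 0.016 without the PDLIM2 array 2. PDLIM2 minus mock was -0.038 between the arrays numbered 1 and -0.28 between those numbered 2. Leaving an array out leaves 1 array alone in its group and unbalances the numbers, so such means are given without a test in this paragraph. Hypoxia and glycolysis genes had a mean of -0.083 over 24 genes (camera, adjusted p = 0.128), with the glucose transporter gene SLC2A1 at -0.40 and PFKFB4 at -0.37. The mean of this list was -0.16 without the PDLIM2 array 2 and -0.0072 without the PDLIM2 array 1. Cholesterol synthesis genes had a mean of -0.057 over 15 genes, with SC5D and HMGCS1 both at -0.35, values that ranged from -0.63 to -0.077 and from -0.62 to -0.082 with an array left out. The mean of the cholesterol list was -0.29 without the PDLIM2 array 2 and 0.18 without the PDLIM2 array 1. It was -0.21 between the arrays numbered 1 and 0.096 between those numbered 2. Cell cycle genes had a mean of -0.039 over 29 genes, with the replication licensing genes CDT1 at -0.47 and MCM5 at 0.44, and a mean of -0.12 without the PDLIM2 array 2. Interferon-stimulated genes had a mean of -0.034 and a median of 0.038 over 27 genes, with OASL at -0.78 and IFIT2 at -0.51, values that ranged from -1.12 to -0.45 and from -0.97 to -0.053 with an array left out. PDZ and LIM domain relatives and partners of PDLIM2 had a mean of -0.074 over 11 genes, with ACTN4 at 0.24 and PDLIM5 at -0.24.

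List means of genes that mark cell types lay between -0.0092 and 0.084 log2 units. Genes of the Hodgkin and Reed-Sternberg phenotype had a mean log2 difference of 0.013 over 27 measured genes, with TRAF1 at 0.28 and CD80 at 0.37, and camera, which compares with all other genes, gave it the lower direction without a call. B-cell programme genes had a mean of 0.084 over 25 genes, with the class II transactivator gene CIITA at 0.39 and EBF1 at -0.35. Antigen presentation genes had a mean of 0.066 over 20 genes, with CIITA again and TAPBP at 0.40. Some of the HLA genes among them are closely similar, so the values of their probes are uncertain. Markers of T and NK cells had a mean of -0.0092 over 5 measured genes, with TBX21 at 0.28 and GZMB at -0.15, and myeloid markers a mean of 0.042 over 9 genes, with CD68 at -0.46 and ITGAM at 0.22. Genes of p53 and apoptosis had a mean of 0.037 over 19 genes, with PMAIP1 at -0.35 and TP53I3 at 0.37. Ribosomal protein genes had a mean of -0.00017 over 23 genes, with RPL37 at 0.25 and RPS14 at 0.15. No member of these 7 lists passed the test in limma, over all probes or adjusted over the list alone. With an array left out, the value moved by over 1.5 times for 20 of the 32 members named from the 17 lists.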

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

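The lists without FOSB and without BAG3 were chosen after seeing the data, the other alternatives before. The brighter PDLIM2 probe kept its direction in every fit run, from 0.14 to 0.48 with an array left out, and the filter at the 75th percentile gave no value for it. The counts of 0 higher and 0 lower probes held in limma under no filter, the 75th percentile, quantile normalization, median centring, limma-trend, the robust prior and the offset. The deposited arrays already shared nearly the same quartiles. Quantile normalization and median centring could therefore change little, and they do not test the normalization. Their values are also among those of the named genes counted below. Same-numbered arrays share only their number in the labels. With the replicate block the fit called 0 probes higher and 1 lower (FOSB, -2.10, adjusted p = 0.0375) and gave 370 lower and 104 higher probes past 1.5-fold, and deviations from the group means of same-numbered arrays correlated across probes (r = 0.476, probes not being independent). The block changed no list call. On the simulated arrays that share a shift by number, the replicate block recovered 100 (own variance) and 89 (prior variance) of the 100 2-fold changes with 41 and 28 false calls, where the fit without it recovered 4 and 0 with 0 false calls, so 0 calls do not exclude changes of that size. With an array left out, 1 array stands alone and is assumed to vary like the others, and the ranges were 0 to 163 probes called higher, 0 to 647 called lower, 110 to 682 and 182 to 1263 past 1.5-fold, and 1 to 4 lists lower. Without the PDLIM2 array 1 the counts were the highest of each range of probes. The offset of 50 gave 46 and 152 probes past 1.5-fold. The cause of these moves was not tested. Lists called lower were 0 at the 75th percentile, with an estimated correlation and with fry, and 1 with the offset and with the mean over probes. The AP-1 shift, called at -0.23, was no longer called at the 75th percentile (-0.26, where fewer genes are tested), with the offset (-0.20), an estimated correlation or fry (-0.23 each), the mean over probes (-0.21) or without FOSB (-0.13), its adjusted p over these ranging from 0.0851 to 0.902, and it ranged from -0.32 to -0.14 with an array left out. The heat shock shift was not called at the 75th percentile (-0.26), with an estimated correlation or fry (-0.30 each), or without BAG3 (-0.22), and ranged from -0.54 to -0.053. With an array left out the shifts of lists that changed sign ranged from -0.17 to 0.11 (NF-kB), -0.12 to 0.041 (JAK-STAT), -0.096 to 0.12 (Hodgkin phenotype), -0.031 to 0.20 (B cell), -0.042 to 0.023 (T and NK cell), -0.053 to 0.14 (myeloid), -0.13 to 0.066 (interferon), -0.073 to 0.21 (antigen presentation), -0.12 to 0.043 (cell cycle), -0.073 to 0.15 (p53), -0.34 to 0.016 (unfolded protein), -0.29 to 0.18 (cholesterol), -0.20 to 0.056 (PDZ and LIM) and -0.055 to 0.054 (ribosomal). The myeloid shift was -0.012 at the 75th percentile and the ribosomal shift 0.00036 with median centring. Of 603 values of the 51 named genes under alternatives, 557 kept direction and side of the threshold, 42 passed it without a PDLIM2 array, 1 did with the replicate block, and 3 reversed with an array left out, where GZMB ranged from -0.55 to 0.25, TAPBP from -0.075 to 0.88 and PDLIM5 from -0.50 to 0.024. Dim probes such as those of PDLIM2 are limited by the background, which the values used here do not give.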

Other observations

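The patterns below were found in these data, and the tests of probe brightness and the comparisons of small RNA classes and of each of the AP-1 and heat shock lists within groups were chosen after the results were seen, as were the counts without the genes picked by rule. Small structural RNAs were taken as all tested probes of nucleolar, nuclear, ribosomal, Y, vault and similar RNAs by RefSeq class, and of Cajal body RNAs by gene symbol. These probes tended to higher values with PDLIM2. Of 234 such probes, 149 were higher and 85 lower, with a median log2 difference of 0.096 against 0.016 for 15868 protein-coding probes. The share of higher values was 63.7%, against 53.6% of the protein-coding probes. Without the 9 probes of genes picked by rule, 140 of the remaining 225 were higher and the median was 0.081. The 17 small nuclear RNA probes had a median of 0.76 and 16 of them were higher, among them RNU4-2 at 0.94 (SE 0.29), RNU1-1 at 0.76 (SE 0.26) and RNU6-1 at 0.64 (SE 0.24), which were 0.51, 0.47 and 0.37 without the PDLIM2 array 2. RNU1-1 was 0.49 without the mock array 1. The nuclear RNA RN7SK had 1.06 (SE 0.26) and 0.77 (SE 0.23) on its 2 probes, of which the second was 0.52 without the PDLIM2 array 1, and the Y RNA RNY1 had 0.88 (SE 0.23), or 0.58 without the mock array 2. The 21 Cajal body probes had a median of 0.19, and the 181 nucleolar ones 0.046, with 58.0% of the nucleolar ones higher. No probe of these passed the adjusted threshold in limma, and 50 of the 234 had an unadjusted p under 0.05 (21.4%, against 3.09% of protein-coding probes). Without the 9 probes of genes picked by rule the share was 18.2%.

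Further genes with lower values, chosen after their values were seen and not as a tested group, were the following. CCNG2, a cyclin of arrested cells, read -0.85 (SE 0.16) on its brightest probe and -0.67 (SE 0.32) and -0.24 (SE 0.19) on the others, KLF9 read -0.81 (SE 0.17), the cell cycle inhibitor gene CDKN1B read -0.74 (SE 0.18) and -0.53 (SE 0.23) on its 2 probes, FOXO1 read -0.61 (SE 0.19) and TXNIP, an inhibitor of thioredoxin, read -0.59 (SE 0.17), beside FBXO32 and HBP1. Without the mock array 2 the second probe of CDKN1B read -0.22 and the third of CCNG2 -0.058, and without the PDLIM2 array 1 the second of CCNG2 read -0.20. CREBRF had -1.59 (SE 0.51) on the brighter of its 2 probes, or -0.68 without the PDLIM2 array 2 and -2.49 without the PDLIM2 array 1, and MAP3K8, a kinase of inflammatory signalling, had -1.18 (SE 0.26). In the other direction, the metallothionein gene MT2A had 0.86 (SE 0.22) and the chemokine gene CCL20 had 0.62 (SE 0.18). None of these values passed the adjusted threshold in limma.

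The higher small RNA values were weighed against 2 technical explanations. A shift that follows probe brightness is argued against, since the median of 0.096 lay above all of 10000 random sets of protein-coding probes of the same brightness, whose medians ran from -0.052 to 0.081 with a mean of 0.017, and without the genes picked by rule the median of 0.081 lay narrowly above the highest matched median, 0.078. Arrays that differ in how much small RNA was carried into the labelling are not excluded, as relative to protein-coding probes the small RNA median differed by 0.103 in size (lower in array 2) between the 2 mock arrays, by -0.057 (array 2 minus array 1) between the PDLIM2 arrays and by 0.079 between the groups. Within the groups the classes went opposite ways from array 1 to array 2, the small nuclear RNAs by 0.33 (mock) and 0.74 (PDLIM2) and the nucleolar RNAs by -0.15 and -0.12, so no single recovery factor accounts for both of these moves. Between the groups every class had a median above 0, from 0.046 (nucleolar) to 0.76 (small nuclear), so the moves do not exclude a single factor there. Recovery that differs between arrays, by class or not, and an effect of PDLIM2, which was not tested, stay open and cannot be told apart with 2 arrays per group.

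For the lower AP-1 and heat shock genes, 36 genes in all with a mean of -0.26, a shift with brightness is argued against, since 10000 random gene sets of the same brightness had a mean of 0.0088 and a lowest value of -0.13, and without FOSB and BAG3 the genes had a mean of -0.17. The 2 lists were picked by their call, so their place below all of these sets is no independent evidence that they are lower. Whether stress that differs between single transfections accounts for the heat shock part is not decided. These genes differed by -0.46 between the mock arrays and by 0.486 in size (lower in array 2) between the PDLIM2 arrays. Both moves were larger than the -0.30 between the groups. They went the same way, so they largely cancel in the difference between the groups, which was -0.29 in number 1 and -0.31 in number 2. The AP-1 genes differed by 0.174 and 0.086 (higher in array 2), less than the -0.23 between the groups in size, and the mean of both lists, in which these opposite moves cancel in part, by up to 0.168 in size. For the AP-1 genes such variation and an effect of PDLIM2 cannot be told apart with 2 arrays per group, and an effect on the heat shock genes, which was not tested apart from it, stays open too.

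The lower values of FBXO32, CCNG2, CDKN1B and FOXO1 led to the hypothesis that targets of the FOXO transcription factors are lower with PDLIM2. It was tested on 28 FOXO target genes listed before their values were looked at, of which 23 were measured. Their mean log2 difference was -0.082 (SD 0.21), 12 of the 23 were negative, and camera in limma, as 1 list tested alone, gave p = 0.0517 by the model fitted across genes, not an exact test, and p = 0.165 with an estimated correlation. The test did not reach the threshold, so these data do not decide the hypothesis.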
